A study of Homo sapiens with 2 samples.

How the data were processed

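The series compared chromatin immunoprecipitation with sequencing (ChIP-seq, which maps where a protein sits on DNA) between 2 libraries of LN229, an established human glioblastoma cell line per the series title and the sample labels. The design text of the series calls the cells prostate cells instead, and the title and labels were followed. In 1 library the cells carried SOX4, an HMG-box transcription factor, with a Flag tag and an HA tag. In the other they carried tagged GFP, a fluorescent protein that does not bind DNA in a sequence-specific way. Both were precipitated with the same anti-Flag antibody, per the labels' protocols. Each group had 1 library and no replicate.

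The analysis started from 1 deposited file, the peak list of the SOX4 library. The GFP library had no peak list or read count in the data used here, and no read-level or signal file of either library was analysed. Bowtie 0.12.7, MACS and the genome build hg19 are named in the submitters' processing notes. The MACS version, its settings, the handling of duplicate reads and the removal of any problem regions are not given in the sources used here. The labels name the GFP cells as the negative control, and how that library entered the peak calling is not given in the sources used here. A peak's score is therefore the authors' own value, and no depth, fold enrichment or false discovery rate could be read from the file.

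Each peak has a chromosome, a start, an end, a name and the score that the authors deposited. The score column has no header. The scores begin just above 50 and 100 peaks hold exactly 3100. The peak names show that MACS wrote the list, and MACS of that generation writes a score that rises as the p-value falls, but the scale is not stated and scores were used only to describe, rank and filter peaks within this list, without ratios of scores. Positions are given in hg19, counted from 1.

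Peaks at most 100 kb apart were chained, and a chain of at least 10 peaks was called a cluster. All other peaks are called dispersed. These settings were chosen after the data were seen. To describe how far the clustering departs from an even spread, the peaks were placed at random 1000 times on their own chromosome, between its start and the end of its last peak. Random positions could fall in unsequenced gaps. Density is the number of peaks per Mb up to the last peak of the chromosome, because chromosome lengths of hg19 were not used here. Unsequenced bases are counted in that length, which lowers the density of chromosomes with large gaps. On chromosome 11, where the last peak ends at 99.9 Mb, the stretch after it is left out, which raises the density there. Shares have exact Clopper-Pearson 95% intervals. The fold density of a chromosome is its density of dispersed peaks over that of all other chromosomes except Y, with an interval derived from the exact interval of the share. All of these intervals cover counting error in 1 library only. They treat peaks as independent, which neighbouring peaks are not, so densities were also computed with each chain of dispersed peaks counted once. Peaks are not replicates, and no p-value here tests the effect of SOX4 against GFP.

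The chaining was run on simulated data, with 400 peaks planted in 20 clusters among 1600 scattered peaks. Of the planted peaks 400 were recovered, and 10 scattered peaks were drawn into a cluster. With no planted cluster, 0 clusters were found. The planted peaks lay closer together than the chaining distance, with more per cluster than the minimum, so their recovery was fixed by the rule. It checks the code, not whether sparser clusters would be found. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.

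Before the data were examined, the plan also held the share of peaks at promoters, exons and introns, SOX and other motifs, an open search for short sequences, 18 gene lists and the position of peaks against the SOX4 coding sequence. All of these need an hg19 sequence or annotation, which was not used here, since the gene table at hand was of GRCh38 and coordinates were not converted. Apart from the SOX4 locus, which is named from general knowledge of hg19, no peak was assigned to a gene. The rule for named items, also set in advance, was then applied in the part that needs no annotation: the 10 peaks with the highest score, with ties broken by width. The clusters and the isolated peaks named below were chosen after their values were seen. Alternatives were a score at or above the median and, added after the data were seen, a score of at least 100, the list without chromosome Y and the widest 1% of peaks, chaining distances of 50 kb and 250 kb, minimums of 5 and 20 peaks per cluster, and, for the relation of width and score, the list without the peaks at or above 3100.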

Results

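SOX4 binding was mapped in LN229 glioblastoma cells that expressed Flag-tagged SOX4, with LN229 cells that expressed tagged GFP as the negative control. The comparison asks which genomic regions the anti-Flag antibody enriched in SOX4 cells. Each condition was represented by 1 library, so no value below has a replicate error. The read depth of both libraries is unknown from the peak list, and it could not be told how many reads lie behind any peak.

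The authors' list held 4201 peaks on 24 chromosomes, which covered 6.91 Mb and did not overlap each other. The median peak was 838 bp wide (quartiles 642 and 1422 bp), and the widest spanned 70685 bp on chromosome 16. Scores were strongly skewed. The median score was 79.1, 32.4% of the peaks scored under 60, close to the lowest score in the list, and 5.59% scored 1000 or more. The score was exactly 3100 in 100 peaks and higher in 3. These 103 peaks made up 2.45% of the list and 22.9% of its covered length, with a median width of 11890 bp. Across peaks of this library, which are not independent replicates, width and score had a Spearman correlation of 0.89.

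Peaks were concentrated in a small part of the genome. In all, 2560 of the 4201 peaks (60.9%, 95% interval 59.4 to 62.4%) lay in 82 clusters, which together spanned 20.04 Mb, or 0.66% of the chromosomes up to their last peak. The largest cluster, on chromosome 21 from 9412492 to 10213516, held 147 peaks. The next, on chromosome 7 from 61054332 to 62053450, held 145 peaks and borders the centromere. The cluster on chromosome 4 from 190477642 to 191031358, near the end of the long arm, held 99 peaks. Clusters of 80 peaks each lay on chromosome 1 from 142535443 to 142967703 and on chromosome 2 from 91595109 to 92043086. Both lie beside a centromere or its heterochromatin. The placements of clusters against centromeres and chromosome ends rest on general knowledge of hg19. The 10 largest clusters held 886 peaks, 21.1% of the list.

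Random placement of the same peaks on the same chromosomes gave between 0 and 24 clustered peaks in 1000 draws, against 2560 observed (one-sided permutation p = 0.001, the smallest that 1000 placements can give). The fullest 1 Mb bin, chromosome 7 from 61 to 62 Mb, held 131 peaks, while the fullest bin of any random placement held 17. Bins with 20 or more peaks numbered 45 and held 52.1% of all peaks. These tests describe this list and compare it with an even spread, and do not compare SOX4 with GFP.

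**Figure D1:**
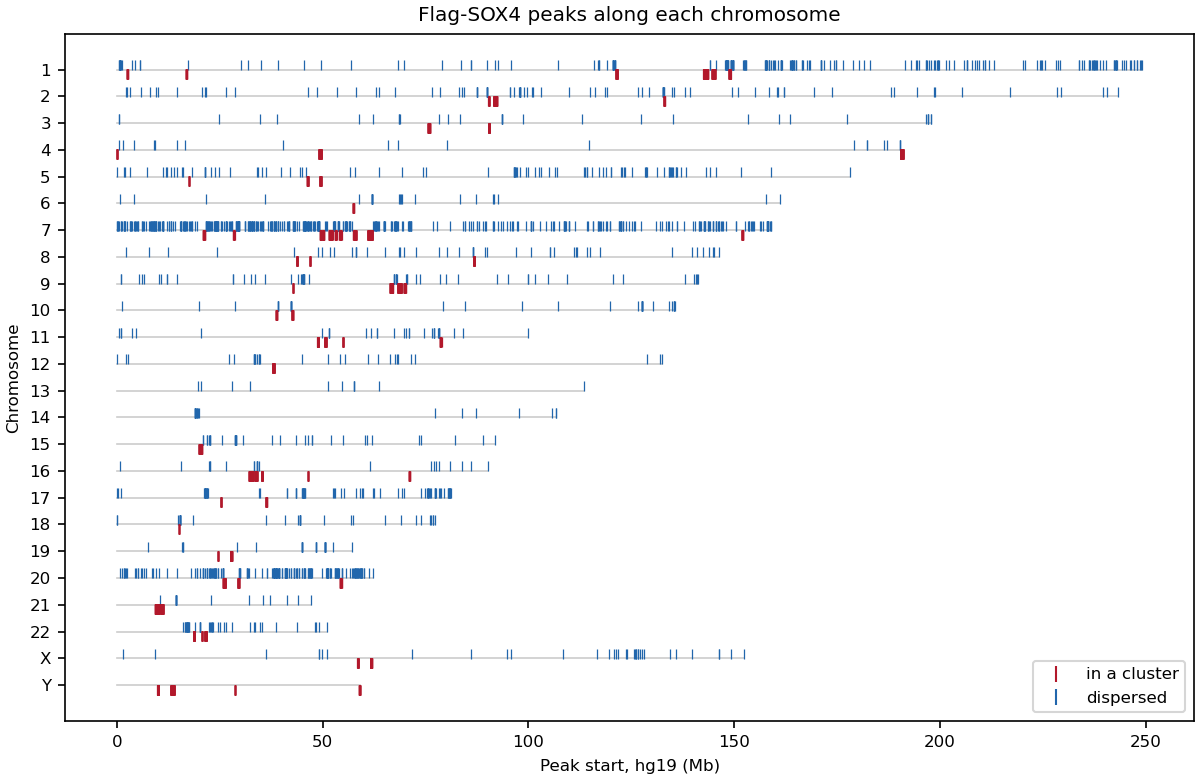
Position of each of the 4201 peaks along its chromosome (x axis, start in Mb of hg19; y axis, chromosome), with peaks of a cluster in red below the line and dispersed peaks in blue above it. The 82 clusters appear as short red blocks, and blue marks are densest on chromosomes 7 and 20.

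Clustered peaks were wider and scored higher than dispersed peaks. Their median score was 114 (quartiles 68.5 and 265), against 58.4 (quartiles 52.96 and 72.6) for the 1641 dispersed peaks. Their median width was 1100 bp against 670 bp. A score of 100 or more was held by 55.9% of the clustered peaks (95% interval 53.9 to 57.8%) and by 14.6% of the dispersed peaks (12.9 to 16.4%). Of the 103 peaks at or above 3100, 72 were clustered (69.9%, 60.1 to 78.5%). A score of 3100 or more was reached in 36 of the 82 clusters. In 9 clusters the highest score was under 120, and 6 of these lay on chromosome 7 and 1 on chromosome 20. Peaks covered only 1.81 to 2.65% of the span of those 7 clusters, with median scores from 53.04 to 61.8, close to the median of the dispersed peaks. The largest, on chromosome 7 from 51482984 to 52447539, held 30 peaks.

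The 10 highest-scoring peaks were clustered, except for 2 on chromosome 10. The highest score, 3220.76, belonged to a 2941 bp peak on chromosome 1 from 143278239 to 143281179. It was followed by chromosome 9 from 66789577 to 66801500 (score 3118.25) and chromosome Y from 13841844 to 13845075 (score 3108.89). The other 7 scored 3100 and were the widest at that score. They lay on chromosome 16 from 46385802 to 46456486, chromosome 4 from 49092900 to 49159910, chromosome X from 61682034 to 61736469, chromosome 2 from 92274227 to 92326305, chromosome 10 from 42354941 to 42397461 and from 39089482 to 39126097, and chromosome 5 from 49405651 to 49441565. All of these 7 lie beside a centromere or its heterochromatin, by general knowledge of hg19. They were picked by width among 100 peaks tied at 3100, so what they share may go with width rather than score. The 2 peaks on chromosome 10 belonged to chains of 7 and 4 peaks and so counted as dispersed.

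The chromosomes differed widely in their number of peaks. Chromosome 7 held 784 peaks, 18.7% of the list (95% interval 17.5 to 19.9%), and chromosome 1 held 575 (13.7%). The order of these 2 depended on weak peaks: among peaks at or above the median score, chromosome 1 held 14.7% and chromosome 7 held 10.3%. Among the 1669 peaks scoring 100 or more, the share on chromosome 7 was 8.81%. Chromosome 13 held 11 and chromosome 14 held 18, and neither had a cluster. On chromosome 21, 214 of 230 peaks were clustered, in 2 clusters, and on chromosome Y all 193 peaks lay in 5 clusters.

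Per Mb and counting peaks of any score, dispersed peaks were most frequent on chromosomes 7 and 20. In number, chromosome 1 with 219 exceeded chromosome 20. Chromosome 7 carried 453 of the 1641 dispersed peaks, or 2.85 per Mb, and chromosome 20 carried 194, or 3.12 per Mb. The other 21 chromosomes without Y had a median of 0.32 per Mb, from 0.097 on chromosome 13 to 0.95 on chromosome 17. Unsequenced bases were counted in the lengths, so the order among these chromosomes may in part reflect their gaps. The density on chromosome 7 was 6.73-fold that of all other chromosomes except Y, chromosome 20 included (95% interval 6.03 to 7.51). That on chromosome 20 was 6.26-fold (5.36 to 7.27), with chromosome 7 among the others. The 2 comparison sets differ, so the folds do not rank the 2 chromosomes. With each chain counted once, the folds were 5.86 (5.08 to 6.74) and 4.82 (3.88 to 5.93). The excess depended on weak peaks on chromosome 7, where it was 8.53-fold (7.40 to 9.81) among dispersed peaks scoring under 60 and 1.88-fold (1.17 to 2.90) among those scoring 100 or more, of which chromosome 7 held 23. On chromosome 20 the same folds were 6.43 (5.22 to 7.85) and 4.50 (2.73 to 7.05), with 21 peaks scoring 100 or more, and these intervals overlap. The fold on chromosome 20 was 4.07 when peaks were chained over 250 kb, and 3.43 when clusters were formed anew among the peaks scoring 100 or more.

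**Figure D2:**
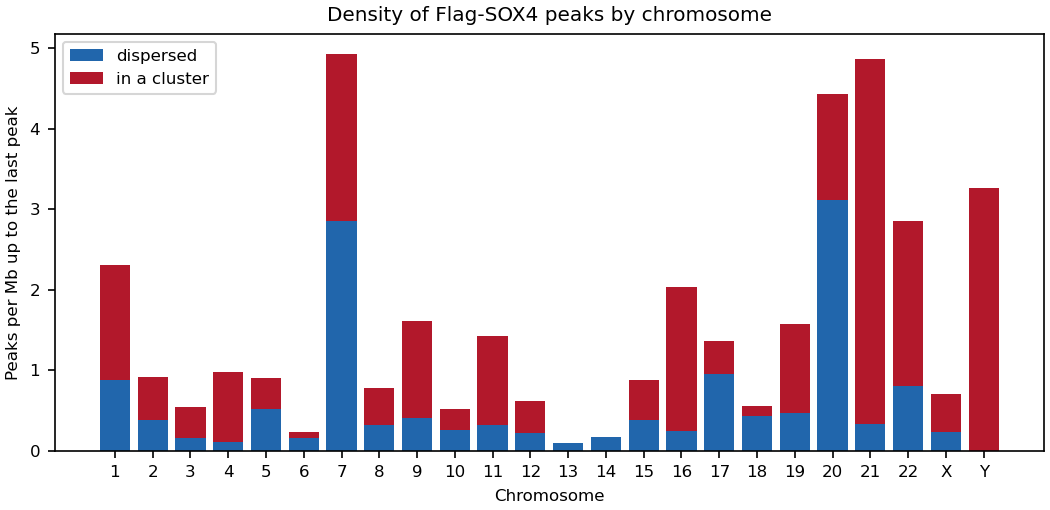
Peaks per Mb up to the last peak (y axis) for each chromosome (x axis), with dispersed peaks in blue and clustered peaks stacked in red. Chromosomes 7 and 20 have 2.85 and 3.12 dispersed peaks per Mb, while the bars of chromosomes 21 and Y are mostly or wholly clustered peaks.

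Some peaks scored high with no other peak within 100 kb. Centromeres and unsequenced gaps of hg19 were not located for these peaks. No peak can lie in such a gap, so a lack of neighbours may come from the assembly. The dispersed list had 808 peaks with no neighbour within 100 kb, and 7 of them scored 3100. They were on chromosome 12 from 34829966 to 34856099, chromosome 17 from 22244120 to 22262967, chromosome 18 from 18510901 to 18520763, chromosome 6 from 58773298 to 58780270, chromosome 1 from 224199025 to 224204333, chromosome 8 from 43092510 to 43097747 and chromosome 4 from 68263910 to 68267014. The eighth lay on chromosome 6 from 21594762 to 21596330, with a width of 1569 bp and a score of 1894. By general knowledge of hg19, this interval falls in SOX4, the single-exon gene of the precipitated factor itself. No annotation of that build was used, so its overlap with the coding sequence and untranslated regions was not computed. Its score ranked 2 among the 480 peaks within 20% of its width, whose median was 168. Other peaks among the 15 highest-scoring isolated ones also ranked near the top of their width class. These peaks, the one in SOX4 included, were listed by score, so high ranks follow in part from that choice. A 955 bp peak on chromosome 9 from 72653008 to 72653962 scored 1033, the highest of 1013 peaks of like width, and a 1500 bp peak on chromosome 13 from 19711351 to 19712850 scored 1715 and ranked 3 of 509. For the peak in SOX4, the nearest other peak was 14.5 Mb away. Of the 235 peaks scoring 1000 or more, only 2 lay more than 5 Mb from any other peak. The other was on chromosome 4 from 80273386 to 80274973, with a width of 1588 bp and a score of 1465. Dispersed peaks were sparse on both chromosomes, with 0.16 per Mb on chromosome 6 and 0.10 on chromosome 4. The median of the 21 chromosomes other than 7, 20 and Y was 0.32. These distances were not compared with those of other peaks on the same chromosome, so they do not set the 2 peaks apart.

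**Figure D3:**
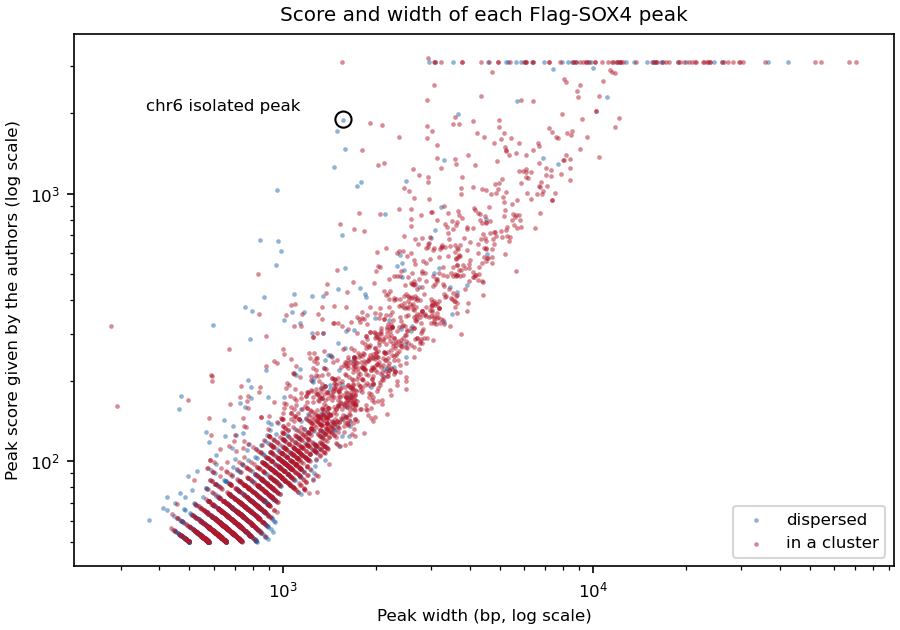
Score given by the authors (y axis, log scale) against peak width in bp (x axis, log scale) for each peak, with clustered peaks in red and dispersed peaks in blue. Most peaks follow a rising band up to the row at 3100, and the circled chromosome 6 peak of 1569 bp stands above that band at 1894, as do other isolated peaks.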

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

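Of the alternatives fixed before the data were examined, those for promoters, introns, motifs and gene lists were not run, because they need an hg19 annotation or sequence. Apart from the median score cut for the number of peaks and the share on chromosome 7, all alternatives here were added after the data were seen. No paired analysis was possible because each group had 1 library. The fold densities stayed above 1 and the correlation positive in the alternatives run. The order of chromosomes 7 and 1 reversed at or above the median score, where they held 10.3% and 14.7% of the peaks. The list held 2102 peaks at or above the median score and 1669 of score 100 or more. Under these 2 cuts, the share of peaks on chromosome 7 fell from 18.7% to 10.3% and 8.81%, the share in clusters rose from 60.9% to 75.9% and 74.96%, the fold density of dispersed peaks on chromosome 7 went from 6.73 to 3.28 and 1.86 and that on chromosome 20 from 6.26 to 3.53 and 3.43, and the correlation of width and score from 0.89 to 0.88 and 0.86. Clusters were formed anew after each cut. Without the peaks at or above 3100 the correlation was 0.88. The share in clusters was 58.8% without chromosome Y and the widest 1% of peaks. It was 54.5% and 67.4% at chaining distances of 50 and 250 kb, and 68.1% and 48.0% with minimums of 5 and 20 peaks per cluster. These minimums gave 128 and 42 clusters in place of 82, and a score of 100 or more gave 50. The fold on chromosome 7 was 7.59 at 50 kb, and that on chromosome 20 was 4.07 at 250 kb and 5.005 with a minimum of 20. The depth of the libraries is unknown, so no limit of detection can be given for a region without a peak.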

Other observations

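Near the start of chromosome 1, peaks from 564795 to 566285 and from 566765 to 568868 scored 136 and 208. This stretch of hg19 is known to carry a nuclear copy of mitochondrial DNA, and the list had no peak on the mitochondrial chromosome itself. Within the first 250 kb of a chromosome, 22 peaks lay on 6 chromosomes. Of these, 14 were on chromosome 4, where they formed a cluster with a highest score of 748, and chromosome 18 had a peak of score 3100 there. Dispersed peaks also changed in density within chromosomes. On chromosome 1, 37 of them lay below 120 Mb (0.31 per Mb) and 138 above 150 Mb (1.39 per Mb, 4.51-fold more). On chromosome 7, 270 lay below 60 Mb (4.50 per Mb) and 183 above it (1.85 per Mb). These boundaries were chosen after the map of peaks was seen.

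The tests in the next paragraphs were chosen after the results were seen, except that on reads from the SOX4 plasmid, which was fixed before the data were examined.

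The isolated peak on chromosome 6, in the SOX4 gene by general knowledge of hg19, is a pattern to follow up, because the cells were transfected with a SOX4 plasmid. Reads from the transfected SOX4 plasmid may map to the genomic coding sequence, and would then give a peak that ends where that sequence ends. The peak was 1569 bp wide, but the comparison with the coding sequence needs an hg19 annotation that was not used here, so this explanation stays open. Binding of SOX4 to its own gene also stays open and was not tested. The GFP library carried no SOX4 plasmid, so subtracting it would not remove such reads.

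The dense clusters are the second pattern. Random placement of the peaks put at most 24 peaks in clusters, against 2560 in the list, which argues against an even spread. Joining peaks at most 5 kb apart left 2074 peaks and 27 clusters in place of 82, a fall that joining brings about whether the peaks are fragments of a wide stretch or separate sites. The share of joined peaks in clusters was still 18.5%, against at most 0.48% in 100 random placements of the joined peaks, so splitting of wide stretches over such distances is not the whole cause, and whether it is part of it stays open. A candidate explanation that was not tested is repeated sequence missing from the assembly, whose reads pile up on the few copies present. It is raised because several clusters named above lie beside a centromere or its heterochromatin, by general knowledge of hg19. How many of the 82 clusters do so was not counted. SOX4 binding in these regions was not tested either, and both explanations need the sequence and the read depth of the GFP library. That library was of the same cell line and would be open to the same pile-ups. Their part in the list therefore depends on how it entered the peak calling, which is not given.

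The third pattern is the excess of dispersed peaks on chromosomes 7 and 20. Among the peaks left after clusters were taken out, the excess was not confined to a few 5 Mb stretches. The 3 fullest of 32 5 Mb bins held 20.1% of the dispersed peaks of chromosome 7. On chromosome 20 the 3 fullest of 13 bins held 42.8%. Every 5 Mb bin of both chromosomes held some, and outside the 3 fullest bins the densities were 2.51 and 2.35 per Mb. Clusters had been taken out beforehand. Among them were 6 on chromosome 7, all below 60 Mb, and 1 on chromosome 20, each with a highest score under 120. A low share in the fullest bins is therefore partly built in, and the test does not cover those stretches. More copies of the chromosome in these cells may lift background over the threshold. The GFP library was of the same cell line and would share such copies. Whether they could act here therefore depends on how that library entered the peak calling, which is not given. Gain of chromosome 7 is common in glioblastoma, the origin given by the title and sample labels though not by the design text. Dispersed peaks on chromosome 7 were denser below 60 Mb (4.50 per Mb) than above it (1.85 per Mb), a boundary chosen after the map was seen. Whether extra copies of the whole chromosome alone could give that difference was not tested. Among dispersed peaks of score 100 or more the excess on chromosome 7 was 1.88-fold (1.17 to 2.90), below the 6.73-fold among all dispersed peaks, while on chromosome 20 it was 4.50-fold (2.73 to 7.05) against 6.26-fold (5.36 to 7.27), or with each chain counted once 4.51-fold (2.40 to 7.81) against 4.82-fold (3.88 to 5.93) and 3.43-fold when clusters were formed anew after the score cut, so whether it fell there depends on how peaks are counted and grouped. Copy number was not measured here, and SOX4 sites present in more copies would also pass the threshold more often, so background and binding cannot be told apart for these peaks.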
